A study of Rattus norvegicus with 28 samples.

How the data were processed

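The series profiled poly(A) RNA from punches of rat orbitofrontal cortex and central amygdala after self-administration of methamphetamine (meth) or saline. The 16 orbitofrontal libraries were analysed; the 12 listed central amygdala samples were not analysed here. Each library held RNA pooled from 2 Sprague Dawley rats, so a replicate is a separate pool of animals. The groups were saline or meth at withdrawal day 2 and at withdrawal day 35, with 4 libraries each. The labels call the orbitofrontal time points short and long, and the days were taken from the series' design text.

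Per the labels' protocols, libraries were made with a TruSeq RNA v2 poly(A) kit and sequenced on an Illumina HiSeq. Per the submitters' processing notes, the tools were TopHat, HTSeq and limma and the genome build was rn4. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are raw counts per gene, one file per library, with no normalization. Each file holds 26405 Ensembl gene identifiers and 5 summary rows of HTSeq. Those rows were left out of library sizes and tests. They took 31.13 to 32.61% of all rows' reads. Most were reads assigned to no counted feature (20.89 to 22.35%) and reads with several alignments (9.17 to 10.29%). Multi-mapping reads were thus not counted to genes, and levels of near-identical gene copies are understated.

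The files do not pair identifiers with gene names, and 0 of the 26405 identifiers matched the gene table at hand, whose column of Ensembl identifiers is empty. The 36 gene lists and the rule for named genes fixed before the data were examined could therefore not be run. That rule named, per comparison, up to 8 genes in each direction by p-value, members of called lists and 5 fixed genes, all by symbol. In its place, the 2 identifiers with the smallest p-value in each direction between meth and saline at day 2 were followed through all comparisons, a choice made after the files were seen. No coordinates are given.

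Gene counts per library ranged from 20.33 to 48.47 M (M, the SI prefix mega). Genes were filtered with edgeR's filterByExpr at its defaults, which kept 15413 genes. Counts were scaled with TMM, whose factors ranged from 0.985 to 1.018, and 1 model of 4 group means over all 16 libraries was fitted with glmQLFit (robust) and tested with glmQLFTest (edgeR 4.0.16, R 4.3.3). The contrasts were meth against saline at each day, their difference, their average, and day 35 against day 2 within each drug group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors of log2 fold changes are the fold change divided by the square root of the quasi-likelihood F. Levels are CPM computed from the deposited counts with TMM-scaled library sizes.

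The 4 libraries of a group carry 1 index and sit on lanes 1 to 4, so each of the 24 within-group pairs was checked for being 1 library sequenced again. No pair was identical, and the chi-square of the counts over genes with at least 20 reads per pair was 5.19 to 17.01 times its degrees of freedom, so all were kept as separate replicates. Each lane held 1 library of every group, which pairs the libraries by a shared lane in the labels. Deviations from the group means correlated by 0.012 on average over the 24 same-lane pairs (range -0.174 to 0.158) and by -0.004 over the 72 other pairs; 6 of 16 libraries correlated best with their own lane. The index is the same within a group and differs between groups, so index and group cannot be separated. The rats were run in separate cohorts per the design text, but no label ties a library to a cohort.

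The pipeline was tested on simulated data drawn from the real gene means, library sizes and dispersions, with 200 genes changed per comparison. With fewer genes changed, the Benjamini-Hochberg adjustment is stricter and a smaller share would be recovered. In the comparison of meth with saline at day 2, 43% of 100 genes changed 1.2-fold and 82% of 100 changed 1.5-fold were recovered among 15349 genes tested, with 5 false calls. For day 35 against day 2 these shares were 39% and 77% in saline rats, and 34% and 71% in meth rats. For meth against saline at day 35 they were 45% and 80%, and for the difference of the meth effect between days 20% and 65%. Alternatives were median-ratio size factors, no filter or a filter at 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom 3.58.1, lane as a block, fits of only the groups compared, and leaving out each library. Added after seeing the data were thinning all libraries to 20.33 M gene counts, voom with sample weights, 1 surrogate variable from svaseq (sva 3.50.0), and leaving out the 2 libraries farthest out on the first principal component. The surrogate variable was first computed on counts not scaled for depth; after its results were seen it was computed again on scaled counts, and both versions are reported. A test for swapped labels of 2 libraries was likewise replaced, and then replaced again, after its results were seen, and all 3 versions are reported. An adjusted p that DESeq2 left empty was not counted as a lost call.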

Results

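RNA-seq gene counts were compared in the orbitofrontal cortex, a frontal region that takes part in evaluating rewards and their cues, of rats that had self-administered methamphetamine (meth), a psychostimulant, or saline. Tissue was taken at withdrawal day 2 or day 35, early and late in the period over which meth craving is known to grow (incubation of craving). Each of the 4 groups held 4 libraries. Gene counts averaged 22.7 ± 1.56 M (SD, n = 4) in day 2 saline, 33.6 ± 5.81 M in day 2 meth, 37.2 ± 7.73 M in day 35 saline and 41.3 ± 3.16 M in day 35 meth libraries. The day 2 saline libraries were thus the shallowest (20.33 to 23.54 M), and 17434 to 18371 genes had at least 1 count per library. The spread between replicates was small, with a common biological coefficient of variation of 6.25%. Genes are known here only by Ensembl identifier, so groups of genes are described by their direction, size and level and not by function.

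The first comparison asked which genes differed between meth and saline rats at withdrawal day 2. In meth rats 13 genes were higher and 4 were lower, of 15413 tested. The higher genes differed by 1.13- to 1.58-fold (median 1.21), and the lower genes by 1.14- to 1.34-fold (median 1.18). All 13 higher genes had their highest mean of the 4 groups in day 2 meth libraries, and all 4 lower genes had their lowest mean there, an order favoured by picking genes that differ between the day 2 groups. ENSRNOG00000012404 rose from 24.2 ± 1.52 to 38.4 ± 1.60 CPM (SD, n = 4 each), a log2 fold change of 0.66 (SE 0.065, edgeR quasi-likelihood adjusted p = 7e-05). ENSRNOG00000013552 rose from 29.4 ± 1.79 to 38.8 ± 1.48 CPM (log2 fold change 0.40, SE 0.054, edgeR adjusted p = 0.0031). Among the lower genes, ENSRNOG00000050983, an abundant transcript, fell from 1330 ± 47.9 to 1120 ± 39.4 CPM (log2 fold change -0.25, SE 0.040, edgeR adjusted p = 0.013). ENSRNOG00000027194 fell from 180 ± 7.26 to 153 ± 8.57 CPM (log2 fold change -0.24, SE 0.039, edgeR adjusted p = 0.013). For each of these 4 genes the 4 meth libraries lay outside the range of the 4 saline libraries. The called genes were more abundant than the genes tested, with median levels of 78.8 CPM for the higher and 382 CPM for the lower genes against 17.8 CPM. The count fell to 6, 8 and 10 genes without day 2 meth replicate 2, day 2 meth replicate 4 and day 2 saline replicate 13, and to 4 without both of the last 2, while DESeq2 called 113 genes, 46 higher and 67 lower, 12 of them among the 17. DESeq2 gave an adjusted p to 5484 genes in this comparison, against 15413 in edgeR, and ENSRNOG00000012404 and ENSRNOG00000013552 were not among them. Without day 2 meth replicate 2 or 4, ENSRNOG00000050983 (edgeR adjusted p = 0.061 and 0.054) and ENSRNOG00000027194 (0.061 and 0.061) no longer passed, nor did the latter in a fit of the day 2 libraries alone (edgeR adjusted p = 0.093), and without day 2 meth replicate 4 and day 2 saline replicate 13 together neither they (0.13 each) nor ENSRNOG00000013552 (0.065) passed.

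**Figure D1:**
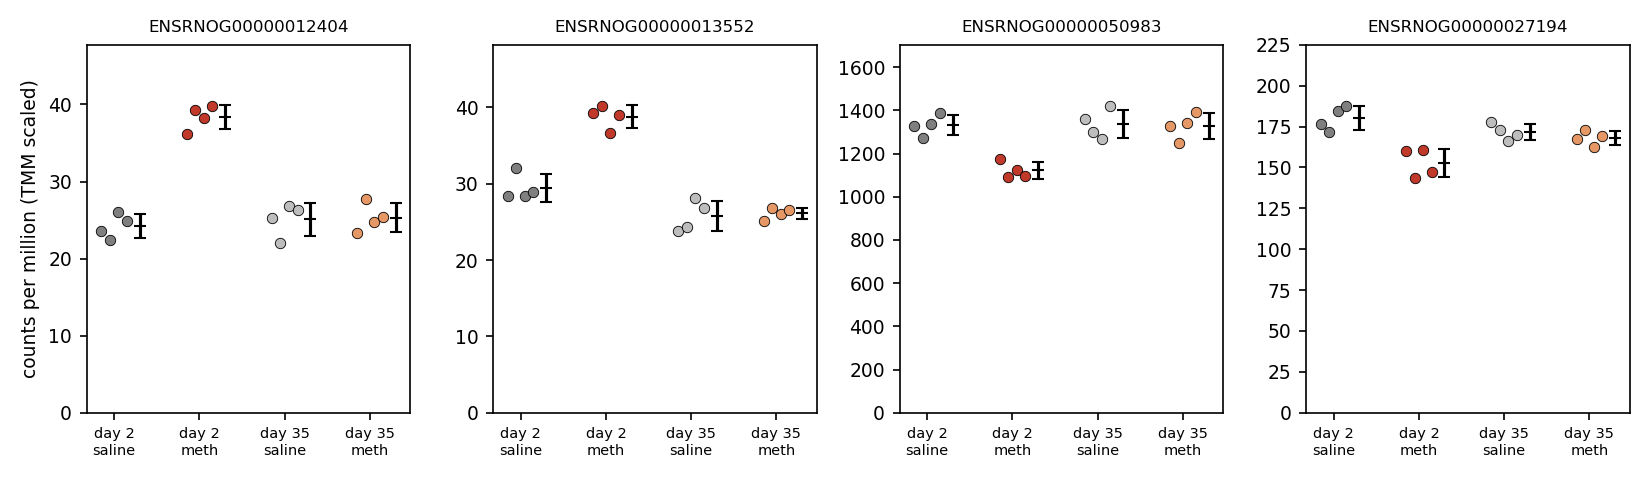
Levels of the 4 followed genes in every library. Points are libraries in TMM-scaled CPM (vertical axes start at 0), and the bar beside each group of 4 is the mean with 1 SD. For ENSRNOG00000012404 and ENSRNOG00000013552 the 4 day 2 meth libraries lie above all 12 others, and for ENSRNOG00000050983 and ENSRNOG00000027194 below all 12 others.

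At withdrawal day 35, no gene was called between meth and saline rats with edgeR. edgeR and limma-voom called 0 of 15413 genes and DESeq2 called 1, and 902 genes had an unadjusted p under 0.05, where 771 are expected with no difference. The 4 genes followed from day 2 were close to equal between the groups. ENSRNOG00000012404 stood at 25.3 ± 1.87 CPM in meth and 25.1 ± 2.16 CPM in saline rats, a log2 fold change of 0.01 (SE 0.063). ENSRNOG00000013552 stood at 26.1 ± 0.709 and 25.8 ± 2.02 CPM (log2 fold change 0.02, SE 0.053), and ENSRNOG00000050983 at 1330 ± 59.9 and 1340 ± 66.4 CPM (log2 fold change -0.01, SE 0.040). Of the 13 genes higher in meth rats at day 2, 5 had a positive and 8 a negative fold change at day 35, with a median of -0.05 on the log2 scale. Differences of 1.2-fold were recovered for 45% of genes in simulated data for this comparison, where 200 genes were changed. The share would be lower with fewer genes changed, so 0 genes called does not show that none differed. Without day 35 meth replicate 7, 1 gene was called.

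Whether the meth effect itself differed between the days was tested directly. The effect was lower at day 35 than at day 2 for 19 genes and higher for 2, by up to 1.80-fold and 1.70-fold. All 19 of the first group had a positive fold change at day 2 (median 0.24 on the log2 scale), and 18 of them a negative one at day 35 (median -0.12); genes picked for a lower effect at day 35 than at day 2 tend toward these signs by the way they were picked. In 17 of the 19 the highest group mean was in day 2 meth libraries, and in 15 the lowest was in day 35 meth libraries. ENSRNOG00000012404 was among them, with a difference of effects of -0.65 (SE 0.090, edgeR adjusted p = 0.013). ENSRNOG00000013552 (-0.38, SE 0.076, edgeR adjusted p = 0.066), ENSRNOG00000050983 (0.24, SE 0.057, edgeR adjusted p = 0.15) and ENSRNOG00000027194 (0.20, SE 0.055, edgeR adjusted p = 0.21) did not pass. With sequencing lane as a replicate block 4 of the 21 genes were called, with median-ratio size factors 8 (0 higher and 8 lower), with DESeq2 78 (22 higher and 56 lower), and without day 2 meth replicate 4 and day 2 saline replicate 13 together 0. The count was 17 without day 2 meth replicate 1 and between 0 (without day 2 saline replicate 14, where ENSRNOG00000012404 had an edgeR adjusted p of 0.056) and 13 (without day 2 saline replicate 16) for the other 15 libraries.

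Averaged over both days, 1 gene was higher and 1 was lower in meth than in saline rats. The higher gene was ENSRNOG00000012404 (log2 fold change 0.34, SE 0.045, edgeR adjusted p = 0.0082), whose difference lay at day 2. The lower gene differed by 1.11-fold. DESeq2 called 31 genes, and 6 of 100 labellings within days, the real one among the 6, gave 2 or more. Without day 2 meth replicate 4 and day 2 saline replicate 13 together 0 genes were called, and ENSRNOG00000012404 missed the threshold there (edgeR adjusted p = 0.10) and in 2 of 27 alternatives in all (adjusted p up to 0.35). Leaving out day 2 saline replicate 14 gave 4 genes, and leaving out day 2 meth replicates 2, 3 or 4, day 35 meth replicate 8 or day 35 saline replicate 9 gave 1.

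The comparison of the 2 days within each drug group asked what changed over withdrawal. In meth rats, 69 genes were higher and 213 were lower at day 35 than at day 2. The higher genes differed by 1.07- to 1.63-fold (median 1.14) and had a median level of 83.1 CPM. The lower genes differed by 1.08- to 3.64-fold (median 1.25) and had a median level of 25.3 CPM. In all, 45 of the 282 genes differed by more than 1.5-fold. Of the 213 lower genes, 210 had their highest group mean in day 2 meth and 193 their lowest in day 35 meth libraries. Of the 69 higher genes, 65 had their lowest mean in day 2 meth and 63 their highest in day 35 meth libraries. Picking genes for a gap between the meth groups favours these orders. ENSRNOG00000013552 fell by 0.57 on the log2 scale (SE 0.052, edgeR adjusted p = 2.7e-05) and ENSRNOG00000012404 fell by 0.60 (SE 0.062, edgeR adjusted p = 8.1e-05). ENSRNOG00000050983 rose by 0.24 (SE 0.040, edgeR adjusted p = 0.0034), and ENSRNOG00000027194 had a log2 fold change of 0.14 (SE 0.039, edgeR adjusted p = 0.079). The count was 153, 179 and 104 without day 2 meth replicates 2, 3 and 4, and 129, 144, 131 and 182 without day 35 meth replicates 5, 6, 7 and 8. DESeq2 called 552 genes and voom with sample weights 605, including 280 and all 282 of these genes.

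In saline rats, no gene was called between day 35 and day 2 with edgeR. edgeR and limma-voom called 0 genes and DESeq2 called 36 (9 higher and 27 lower). An edgeR unadjusted p under 0.05 was found for 1338 genes, where 771 are expected with no difference, and for 2472 genes in meth rats. Differences of 1.2-fold were recovered for 39% of genes in simulated data for this comparison, where 200 genes were changed. The share would be lower with fewer genes changed, so 0 genes called here does not show that none differed. ENSRNOG00000012404 had a log2 fold change of 0.05 (SE 0.066), ENSRNOG00000050983 of 0.01 (SE 0.040) and ENSRNOG00000027194 of -0.07 (SE 0.039). ENSRNOG00000013552 had the largest of these 4 changes, from 29.4 ± 1.79 to 25.8 ± 2.02 CPM (log2 fold change -0.19, SE 0.055, edgeR adjusted p = 0.34). Of the 213 genes lower at day 35 in meth rats, 126 had a negative and 87 a positive fold change in saline rats, with a median of -0.02 on the log2 scale. Of the 69 higher genes, 52 had a positive fold change in saline rats (median 0.04). The counts of 282 and 0 do not by themselves show that the drug groups differ; the direct test of that difference is the comparison of meth effects between days, which called 21 genes. Leaving out day 2 saline replicate 14 gave 2 genes and leaving out day 35 saline replicate 9 gave 1.

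**Figure D2:**
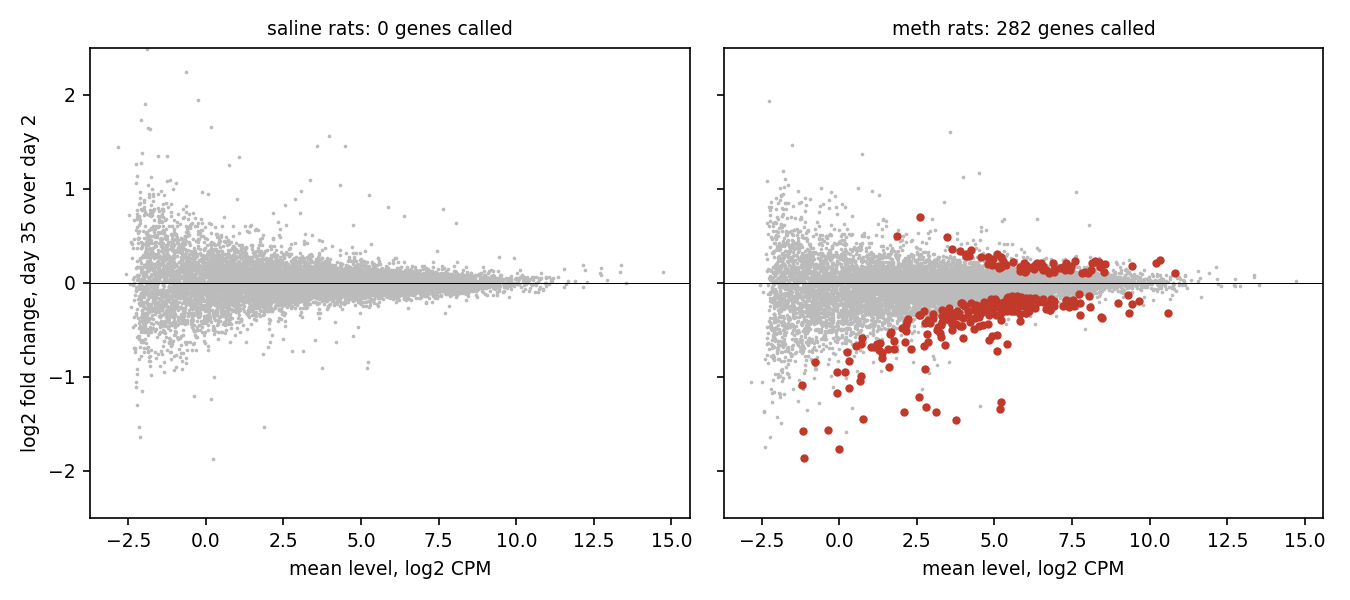
Change from withdrawal day 2 to day 35 against mean level for all 15413 genes tested. The vertical axis is the log2 fold change of day 35 over day 2, the horizontal axis the mean log2 CPM over the 4 groups, and red points are genes with an edgeR adjusted p under 0.05. Saline rats (left) have 0 such genes and meth rats (right) 282, of which 213 lie below 0; 1 gene on the left and 2 on the right fall outside the axis range of 2.5.

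Most genes called between meth and saline at day 2 were also called between the days in meth rats. Of the 13 genes higher in meth at day 2, 12 were among the 213 lower at day 35 in meth rats, and of the 4 lower genes 2 were among the 69 higher ones. Independent lists of these sizes would share 0.18 and 0.0179 genes. Both comparisons use the same 4 day 2 meth libraries with opposite sign, which by itself would tie them together. Over 13560 genes at 1 CPM or more, the fold changes correlated across genes by r = -0.56, and 20 simulations with no group difference gave a mean of -0.49 (range -0.53 to -0.44). The covariance was -0.0112 against -0.00662 in the simulations. With the day 2 meth libraries divided into 2 sets of 2, 1 set for each comparison, no library was shared. The covariance then averaged -0.0053 (range -0.00782 to -0.00366), so part of the tie remained without shared libraries. The divisions reuse the same libraries, so this range does not measure chance. The correlation averaged -0.21 (range -0.33 to -0.13), but sets of 2 carry more noise, so it is not comparable with the values above. Genes are not independent replicates, and no p-value was attached.

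**Figure D3:**
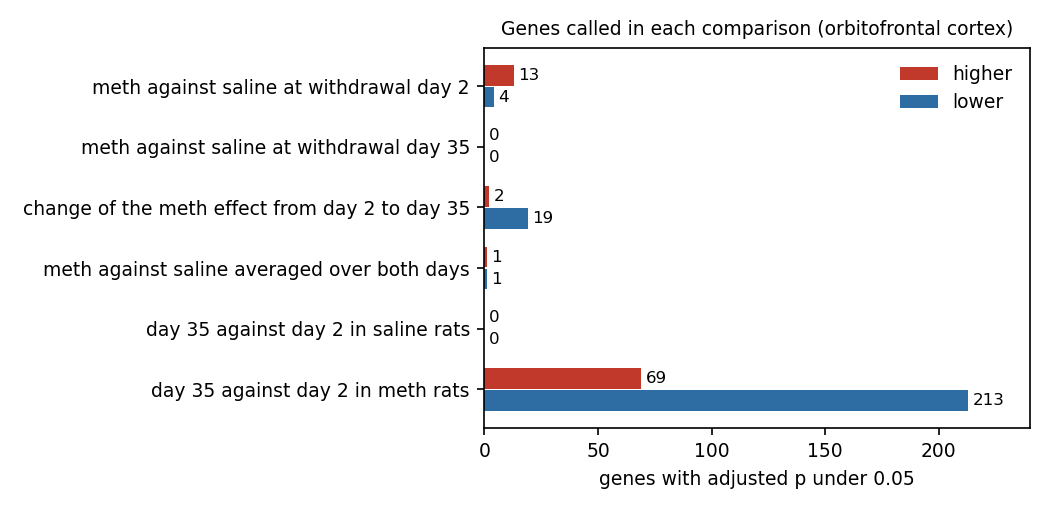
Number of genes called in each comparison, at an edgeR adjusted p under 0.05. Red bars count genes higher and blue bars genes lower in the first-named condition, or with a larger and smaller meth effect at day 35 in the third row. Day 35 against day 2 in meth rats has 69 and 213 genes, and the comparisons at day 35 and in saline rats have 0.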

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

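The tests of exchanged labels and of a hidden factor, the alternatives with thinned counts or a surrogate variable, and the rule that a surrogate variable parting the compared groups completely decides nothing were chosen after the group comparisons, or the result they bear on, had been seen. The fit with lane was fixed before the data were examined, but the bounds for reading it were set after its result was seen. The meth effect differed between withdrawal days for 21 genes by a direct test of the difference, and for ENSRNOG00000012404 by -0.65 on the log2 scale, which missed the threshold in 3 of 27 alternatives (adjusted p up to 0.12). Relabelling meth and saline at random within each day gave at most 5 such genes, so 1 of 100 draws, the real one, reached 21. Such relabelling tests for no meth effect on either day, not for equal effects on both days. The draws ignored the lanes, and the count was 4 with lane as a block. It was 8 with median-ratio size factors, 9 with limma-voom, 78 with DESeq2 (all 21 among them) and 0 to 17 with 1 library left out. Chance is therefore not firmly excluded for this count.

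A pattern to follow up is that 282 genes differed between day 35 and day 2 in meth rats and 0 in saline rats; of the 35 splits of the 8 meth libraries only the real one (1 of 35) gave as many, the next highest giving 1. Lower depth of the day 2 saline libraries is argued against by thinning all libraries to 20.33 M counts, which left 191 genes in meth and 1 in saline rats. Greater noise in saline rats was examined by the covariance of the change over genes between separate sets of the libraries. Noise does not inflate that covariance on average, and it stayed larger in meth rats by at least 0.00771 with any 1 library left out. Noise still scatters it, as splits of the saline libraries other than the real one reached 0.00897. No test of the difference in this covariance between the drug groups was run, so greater noise in saline rats stays open. A single aberrant library is argued against by a lowest count of 104 with 1 library left out, only just above the bound of 100 set in advance; each lane held 1 library of every group, so the 311 genes with lane as a block decide nothing about lane. A batch carried with the index or preparation of a group cannot be told apart from the groups, since each has 1 index, and an effect of meth exposure and withdrawal also stays open, untested.

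A second pattern is that exchanging day 2 meth replicate 1 with day 2 saline replicate 13 called 16 genes, sharing 0 with the 17 of the real day 2 groups. The real groups were the only 1 of 35 splits to reach 17, but the gap of 1 gene is smaller than the change on leaving out 1 library (6 to 21 genes), and 6 of 35 splits reached the real covariance of 0.00329 (highest other 0.00937), so chance is not firmly excluded for the day 2 count. A swap of the 2 labels is argued against by the 16 genes called at day 2 without both libraries. In 13 of them meth replicate 1 lay further toward the other meth libraries than saline replicate 13 did. On a scale from 0 (other saline) to 1 (other meth), saline replicate 13 had a median position of 0.074 (quartiles -0.022 and 0.23). Meth replicate 1 had a median position of 0.64 (quartiles 0.28 and 0.84), so for some of these genes it lay nearer the other saline libraries. That test came after 2 others that did not decide, in which 26 of the 50 genes with the smallest p without both libraries differed the same way between them, and 66.3% of 294 genes called between the meth groups lay further toward day 2 meth in meth replicate 1. A hidden factor stays open for the real and for the exchanged groups. With a surrogate variable from scaled and from unscaled counts, 37 and 0 genes were called for the real groups. For the exchanged groups both gave 0. In each pair 1 of the surrogate variables parts the groups completely. For the real groups it is the unscaled one, which followed library depth, from 0.483 at 20.33 M gene counts to -0.408 at 48.47 M. Its 0 genes therefore cannot tell a hidden factor from depth or from the groups. The 37 genes speak only to the factor that the scaled one carries.

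Single libraries stood apart from the other 3 of their group in 7 of 40 sets of 4 values, where chance gives about 1 in 20. The sets share libraries and related measures, so they are not independent and 7 of 40 is not a test. In day 2 saline, replicate 13 had 20.33 M gene counts and replicate 14 had 32.1 CPM of ENSRNOG00000013552. In day 2 meth, replicate 1 had the fewest gene counts (24.97 M) and the fewest genes detected (17806). It also had the highest share of reads with several alignments (10.29%). These replicates 13 and 1 are the 2 libraries of the exchange above. In day 35 meth, replicate 8 had 10.79% of its gene counts in its 10 most abundant genes. In day 35 saline, replicate 9, the deepest library (48.47 M), had 18348 genes detected.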

How the results depend on the processing

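Thinning, sample weights, both surrogate variables and the removal of 2 libraries were chosen after seeing the data; the other alternatives were fixed before the data were examined. The cause of the changes below was not tested. DESeq2 called 113 genes between meth and saline at day 2 (40.7% higher, against 76.5% with edgeR, and from 5484 genes with an adjusted p), 1 at day 35, 78 for the change of the meth effect (28.2% higher, against 9.52%), 31 for the average, 36 between days in saline and 552 in meth rats (38.4% higher, against 24.5%). The change of the meth effect gave 8 genes with median-ratio size factors, 9 with the filter at 1 CPM, 9 with limma-voom, 9 with sample weights and 4 with lane as a replicate block; the block moved no other count by over 1.5 times. Sample weights gave 605 genes between days in meth rats. Thinning gave 1 gene for the average and 1 between days in saline rats. With 1 surrogate variable from scaled counts the counts were 37 at day 2, 36 for the change of the effect, 5 for the average, 2 between days in saline and 536 in meth rats. The version run first, from counts not scaled for depth, gave 0 at day 2, 0 for the change of the effect, 0 for the average and 321 between days in meth rats, and turned the correlation of the day 2 and day 35 meth effects to 0.147; scaled counts replaced it after these values were seen. Without day 2 meth replicate 4 and day 2 saline replicate 13 the counts were 4 at day 2, 0 for the change of the effect, 0 for the average and 119 between days in meth rats. Leaving out each of the 16 libraries in turn gave 6 to 21 genes at day 2, 0 to 1 at day 35, 0 to 17 for the change of the effect, 1 to 4 for the average, 0 to 2 between days in saline and 104 to 305 in meth rats, and correlations of -0.144 to -0.0732. With no filter on low counts, over 20828 genes, the correlation was -0.0113. ENSRNOG00000012404 at day 2 ranged from 0.61 to 0.69 on the log2 scale over the 27 alternatives with an adjusted p (3.7e-06 to 0.059), and missed the threshold in 1, the unscaled surrogate variable. At day 2, ENSRNOG00000013552 missed it in 2 of 27 alternatives (adjusted p up to 0.065), ENSRNOG00000050983 in 4 of 28 (up to 0.62) and ENSRNOG00000027194 in 5 of 28 (up to 0.56). No called fold change of the 4 followed genes changed sign. The 36 gene lists, with their camera and fry alternatives, were not run, as no identifier could be matched to a symbol. At this depth, with 4 libraries per group and 200 genes changed, 20% to 56% of simulated 1.2-fold differences were recovered, depending on the comparison.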

Other observations

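The levels per library of the 294 genes were computed after the exchange of 2 libraries had been seen, and the correlation of the changes over time, the covariances and the principal components were not tied to a prediction of their own. The meth effects at day 2 and day 35, which share no libraries, correlated across the 15413 genes by r = -0.13 (Spearman's rho -0.10). Of 100 labellings within days, 13, the real one among them, gave a value as far from 0 (range without the real one -0.17 to 0.22). The hypothesis that the effect at day 35 opposes that at day 2 over all genes was therefore not borne out. The changes from day 2 to day 35 in saline and in meth rats correlated by r = 0.083 (rho 0.11), which was not tested.

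Over 13560 genes at 1 CPM or more, the covariance of a fold change was taken between separate sets of the libraries. It estimates the variance of differences that the libraries of a group share, which would include any batch carried with the group. It was 0.0124 for day 35 against day 2 in meth rats, a standard deviation of 0.11 on the log2 scale, above all 34 other splits (highest 0.00573). It was 0.00329 for meth against saline at day 2, 0.00162 between days in saline rats and -0.000896 for meth against saline at day 35, which 6, 9 and 23 of 35 splits reached. For the last 2 comparisons, each with 0 genes called, a count over splits decides nothing, since all 35 splits reach 0; the highest other counts were 5 between days in saline rats and 1 for meth against saline at day 35. For the average over both days, 6 of 100 labellings, the real one among the 6, gave 2 or more genes. The highest gave 4, so chance was not excluded.

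Of 294 genes called between the meth groups without day 2 meth replicate 1 and day 2 saline replicate 13, the 8 saline libraries of both days lay between the meth groups, at medians of 0.0605 to 0.152 log2 units above day 35 meth toward the day 2 meth level. The genes were picked for the gap between the meth groups, which tends to place any other group between them. Day 2 meth replicate 1, not used in the picking, lay at 0.191. Day 2 meth replicates 2, 3 and 4, which were used, lay at 0.3, 0.286 and 0.343.

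The first principal component held 13.2% of the variance and had day 2 meth replicate 4 and day 2 saline replicate 13 farthest out at -19.9 and -17.9. On it, day 2 meth replicates 2, 3 and 4 and day 2 saline replicate 13 lay at -3.77 or below. The other day 2 libraries, meth replicate 1 and saline replicates 14, 15 and 16, lay at -2.07 or above. These are the groups formed by the exchange of 2 libraries. Reads assigned to no counted feature made up 21.5 ± 0.471% in day 2 saline, 21.6 ± 0.194% in day 2 meth, 21.7 ± 0.631% in day 35 saline and 21.9 ± 0.237% in day 35 meth libraries (SD, n = 4). Gene counts per library were higher in day 2 meth and in day 35 saline than in day 2 saline libraries, in 4 of 4 libraries each (two-sided exact permutation p = 0.0286 for both, the smallest this design allows), and neither passed after adjustment over 20 tests (0.228).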
